A study of Homo sapiens with 6 samples.

How the data were processed

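The samples are 6 RNA libraries of the human cell line K562, 3 labelled as IRAIN over-expression and 3 labelled as wild type. Per the labels' protocols, total RNA was extracted with the QIAamp AllPrep RNA Mini kit, libraries were made with the TruSeq RNA Sample Preparation kit, and their quality was assessed on an Agilent Bioanalyzer. Reads were aligned with STAR to hg38 (GRCh38), per the submitters' processing notes. The versions of STAR and of the gene annotation are not given in the sources used here.

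The authors deposited a table of raw, whole-number counts per gene for the 6 libraries, with 58440 gene identifiers and no normalization. Its over-expression columns match the labels by name and replicate number, whereas its control columns are named vector with a number, so they were assigned to the control group as a whole and are called here by their column number. A second deposited table, without header or sample name, holds counts of 1 library in the layout of STAR's gene counts, with strand ignored, with read 1 on the gene's strand and with read 1 opposite to it. Its strand-ignored counts equal those of over-expression replicate 2 at all 58440 identifiers. Of its 37352455 reads, 34.7% were counted to genes, 23.7% were unmapped and 29.9% mapped to a single place outside annotated exons. Of the counts assigned by strand, 15.1% lay on the minor strand, so the library marks strand while the deposited counts do not use it. Reads of overlapping genes on opposite strands therefore cannot be separated in the comparison, and 18.9% of the tested genes (3465) had most of their reads on the opposite strand in that library. This share was 8.73% among the changed genes (630) and 65.4% among tested antisense genes. The strand counts were used only to describe single genes and in the tests of the closing section, since they cover 1 library.

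Gene identifiers were matched without their version to GENCODE release 29, the annotation at hand, and to a table of gene names. Of them, 58320 matched GENCODE, 56992 with the same version, 57799 matched the table of names and 120 matched neither. Coordinates are those of GENCODE release 29 on GRCh38.

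Library totals ranged from 11558983 to 13303139 counts in genes. Before averaging, each pair of libraries was compared by the chi-square per degree of freedom over genes with at least 20 counts in the pair. Pairs within a group gave 1.36 to 2.31, more than sampling noise, and pairs across groups 12.9 to 14.5. Each library was counted as a replicate, though such values cannot tell separate cultures from technical repeats. Scaling by relative log expression (RLE) moved the median log2 fold change by -0.00229 against the trimmed mean of M-values (TMM).

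The comparison was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test on the deposited counts, two-sided, with TMM factors, the default filterByExpr filter, the group as the sole term and Benjamini-Hochberg adjustment at 0.05. CPM values are counts divided by TMM-scaled library sizes. The SE of a log2 fold change was taken as its size divided by the square root of F. A fold against a group at 0 was computed against a floor of 3 counts over the group, and ratios of counts carry exact 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

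The test, the groups, the alternatives, 44 gene lists and the rule for named genes were fixed before the data were examined. The rule took IRAIN and IGF1R, then the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, with a mean of at least 5 CPM in the higher group and a symbol that is no clone or LOC name. It also took up to 2 risen and 2 fallen genes of smallest p per list, and ABCB1, ABCC1, ABCG2, BCR, ABL1, BCL2L1 and MCL1 in any case. This gave 157 genes with values, of which the report names a part, and some are not reported here. The 38 lists with at least 5 measured genes were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists. With an estimated correlation, camera uses the 4 residual degrees of freedom. The count adjusted over the list alone repeats the Benjamini-Hochberg adjustment within each list.

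Simulated data took the real means and library sizes and the dispersion that the fitted trend gives each gene, with 200 of 18380 genes changed. There the edgeR step called 36% of genes changed 1.2-fold in the right direction, 88% at 1.5-fold, 96% at 2-fold and 96% at 3-fold. Unchanged genes made up 4.82% of its calls. Variation of single genes around the trend was not simulated, and in the data a far larger share of genes (39.3%) was called. These rates therefore need not hold for the real comparison. A simulated list shifted by 1.3-fold was called by camera with both kinds of correlation (adjusted p = 0.00337 with the estimated one), and 0 of 99 unshifted lists were called with the preset one. The simulated genes were drawn independently and none outside the shifted list was changed. This check therefore could not show false calls that correlated genes may give with the preset correlation.

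For positions along the genome, 12381 genes above a mean of 4 CPM on 23 chromosomes were ordered by start, and the median log2 fold change was taken in windows of 50 genes. Windows beyond the 95th percentile of the largest window median in 2000 permutations of gene positions (0.18) were joined into runs. In 100 permuted scans, a planted shift of 100 genes, larger than the median of any run found in the data, was found every time, and 4 scans without one gave a run. Whether smaller or shorter shifts would be found was not checked. The number of permutations was raised after a first, smaller set had put the threshold too low in this check. Each chromosome's median was compared with 2000 random draws of as many genes.

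Alternatives fixed in advance were RLE factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, an adjusted p of 0.01, edgeR's test against a 1.5-fold change, each library left out, and for the lists also the estimated correlation and fry. Alternatives chosen after seeing the data were a GC and length correction, which removes a spline trend on GC content and exon length from each library for the 99.8% of tested genes with both values, the same correction with library sizes and TMM factors taken again after the trend was removed, leaving out chromosomes, and asking for at least 2-fold. Chromosomes 8, 11, 18, 21 and X were picked by eye from a first scan along the genome, before the chromosomes were tested, and of these chromosomes 18 and X did not pass that test (adjusted p = 0.057 and 0.13). Chromosomes 8, 11, 12, 15 and 21, which passed it, were therefore left out as a further alternative. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 served for the remaining steps.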

Results

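The series measured the whole transcriptome of K562, an established human chronic myeloid leukaemia cell line that carries the BCR-ABL1 fusion and expresses erythroid and megakaryocytic genes. Total RNA was sequenced from 3 libraries of cells over-expressing IRAIN and from 3 control libraries. IRAIN is a long noncoding RNA transcribed antisense at the locus of IGF1R, the receptor tyrosine kinase for insulin-like growth factor. The GEO labels call the controls wild type, whereas the columns of the deposited count table call them vector, so whether they carried an empty vector is left open here and they are called controls below. The over-expression libraries held 11558983, 12969218 and 13303139 counts in genes, and the controls held 11893872, 12237415 and 11949606. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

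The series' design text names drug resistance as the subject of the over-expression, and the comparison asks how the transcriptome of K562 differs when IRAIN is raised. IRAIN (ENSG00000259424.1, GRCh38 chromosome 15, 98646951 to 98647371, minus strand, annotated as antisense) stood at 7.99 ± 0.57 CPM (counts scaled to library size; SD, n = 3) in the over-expression libraries and at 0.0276 ± 0.048 CPM (SD, n = 3) in the controls. IGF1R (ENSG00000140443.13, chromosome 15, 98648539 to 98964530, plus strand) rose from 30.1 ± 0.17 to 48.7 ± 1.2 CPM (SD, n = 3 each). Over all tested genes, IRAIN and IGF1R included, 3734 were higher and 3483 lower. By camera with a preset correlation, ATF4 target genes, STAT5 targets, erythroid genes and ribosomal protein genes were higher as lists, and heat shock, megakaryocyte and DNA replication genes lower. With an estimated correlation none of these lists passed (adjusted p = 0.071 to 0.2), and the megakaryocyte call was also lost without chromosomes 8, 11, 18, 21 and X (adjusted p = 0.2), though not without chromosomes 8, 11, 12, 15 and 21 (0.0037). The steepest falls included KCND2, from 43.5 ± 2.1 to 0.518 ± 0.17 CPM, and the steepest rises EPB41L3, from 0.355 ± 0.2 to 32.1 ± 1.9 CPM (SD, n = 3 each). Of the genes tied to drug response that were named before the data were examined, BCR and ABL1 did not pass the test, BCL2L1 rose and MCL1 fell. Of the drug efflux pumps named in the same way, ABCC1 fell slightly, ABCB1 did not pass the test and ABCG2 had too few counts to test.

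In all, 7217 of 18380 genes tested (39.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. Most differences were small: 73.8% of the changed genes differed by less than 1.5-fold, while 876 differed by at least 2-fold, 314 of them lower and the rest higher. The CPM ranges of the groups did not overlap for 8727 genes (47.5%), where chance gives 10% for 3 against 3. The replicates were tight, with a biological coefficient of variation of 2.58%. By annotated type, 3086 of 12465 protein-coding genes rose and 2911 fell, and 183 of 1086 long intergenic noncoding RNA genes rose and 134 fell. DESeq2 called 4805 genes, 2463 of them higher. In a test against a 1.5-fold change, edgeR called 689 genes.

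For IRAIN, the counts were 97, 94 and 106 in the over-expression libraries and 0, 0 and 1 in the controls. The pooled shares differed 283-fold, with an exact 95% interval of 50.4 to 11200 that covers counting error only. The fitted log2 fold change was 7.73 ± 0.42 (SE; edgeR adjusted p = 8.1e-24), and it became 9.62 without the control library that held the single count and 7.07 by limma-voom. IGF1R counts were 557, 633 and 624 against 362, 369 and 364, a log2 fold change of 0.69 ± 0.062 (SE; edgeR adjusted p = 1.1e-14), and IGF1R did not pass edgeR's test against a 1.5-fold change (adjusted p = 0.23). The deposited counts ignore strand, so reads of IGF1R and of antisense transcripts inside it cannot be told apart in these values. The annotated IRAIN interval ends before the start of IGF1R, and any part of the transcript outside that interval is not counted to IRAIN.

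**Figure D1:**
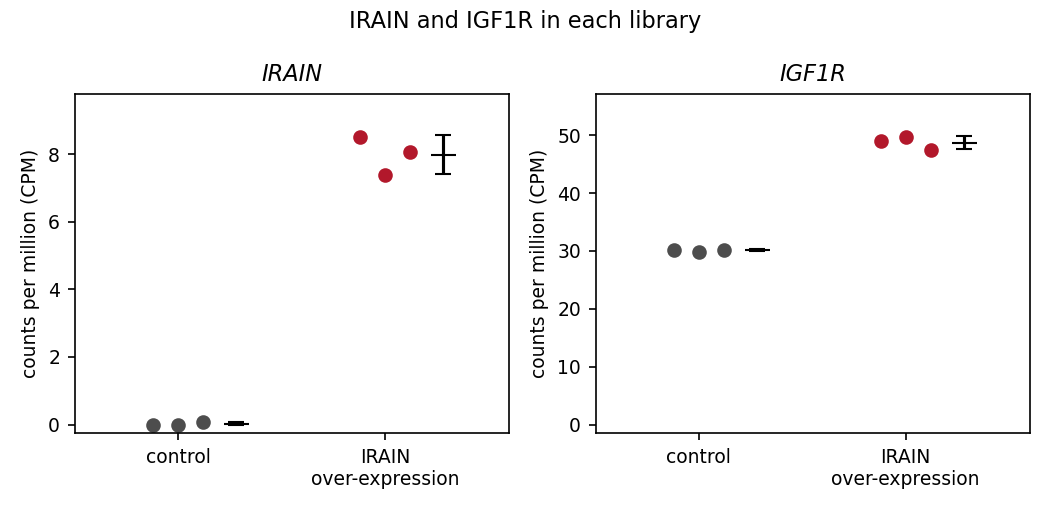
Expression in CPM (linear vertical axes) of IRAIN and IGF1R, with 1 point per library for the 3 control and the 3 IRAIN over-expression libraries; bars beside the points give mean and SD. IRAIN averaged 7.99 CPM against 0.0276 and IGF1R 48.7 against 30.1, with no overlap between the groups for either gene.

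Among genes of the insulin-like growth factor axis, 7 of 12 measured rose and 3 fell (7 and 4 adjusted over the list alone), and the list as a whole did not pass the test (camera adjusted p = 0.13). Log2 fold changes from here on carry their SE. IRS1, a docking protein of the activated receptor, rose by 2.44 ± 0.15, and the ligand gene IGF1 by 0.92 ± 0.071. IGFBP4, which binds the ligands, fell by 0.85 ± 0.081, and IGF2BP1, an RNA-binding protein, fell by 0.25 ± 0.028. Of the chromosomal neighbours of IGF1R, 4 of 7 rose and none fell, including ARRDC4 (0.65 ± 0.048) and MEF2A (0.28 ± 0.054; camera adjusted p = 0.044). That call was lost with an estimated correlation (adjusted p = 0.2), without over-expression replicate 1 (0.057), without the control column numbered 3 (0.063) and without chromosomes 8, 11, 18, 21 and X (0.052). For every list below without a second count, the count adjusted over the list alone was the same.

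The 10 largest rises among genes at 5 CPM or more in the higher group included SPATA31C2, which had 208 counts in the over-expression libraries and 0 in the controls. That is at least 66.1-fold higher against a floor of 3 counts over the control group, for counting error only. SPATA31C2 belongs to a family of near-identical copies, and 88.3% of its reads lay on the opposite strand in the library with strand counts, so the source of these reads is uncertain. Besides IRAIN, they included EPB41L3, a membrane skeleton protein (6.45 ± 0.18), IL1R1, a receptor for interleukin-1 (4.58 ± 0.17), and VCAN, a matrix proteoglycan (4.46 ± 0.28). VCAN was low in the controls, and its value became 5.44 without the control column numbered 1 and 5.22 by limma-voom. The metalloproteinase ADAM19 (3.56 ± 0.088), the deacetylase HDAC9 (3.20 ± 0.24), the ubiquitin ligase HECW2 (3.03 ± 0.045), GYG2 (3.01 ± 0.18) and the collagen COL15A1 (2.96 ± 0.1) completed the group. HECW2 was the most abundant of them, at 240 ± 4 against 29.5 ± 1.8 CPM (SD, n = 3 each).

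The 10 largest falls included the potassium channel gene KCND2 (-6.39 ± 0.15), ACSS1, a mitochondrial acetyl-CoA synthetase (-5.13 ± 0.23), TMPRSS15 (-5.12 ± 0.37) and the pyruvate dehydrogenase kinase PDK3 (-4.98 ± 0.28). ACSS1 had few reads in the over-expression libraries, and its value became -6.47 without over-expression replicate 2. SHISAL1 (-4.65 ± 0.22), the chromatin protein HMGA2 (-4.31 ± 0.13), FAM9B (-4.09 ± 0.3), VWC2L (-3.47 ± 0.29) and ITIH5 (-3.32 ± 0.072) fell as well. The few SHISAL1 and VWC2L reads of the library with strand counts all lay on the opposite strand. RAB27B, a small GTPase of secretory granules in platelets and other cells, dropped from 175 ± 2.2 to 15.5 ± 2.1 CPM (SD, n = 3 each).

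Erythroid genes were mostly higher: 20 of 29 rose and 3 fell (20 and 4 adjusted over the list alone; camera adjusted p = 5.4e-07, and adjusted p = 0.071 with an estimated correlation). The mitochondrial iron carrier SLC25A37 rose by 0.61 ± 0.029 and the Rh-associated glycoprotein RHAG by 0.53 ± 0.027, whereas the transferrin receptor TFRC fell by 0.35 ± 0.026. Of 10 heme biosynthesis genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.18 with an estimated correlation). ALAS2, the erythroid form of the first enzyme of the pathway, rose from 26.3 ± 0.77 to 79.4 ± 1.8 CPM (SD, n = 3 each), and FECH, which inserts the iron, rose by 0.36 ± 0.04. The heme list lost its call without chromosomes 8, 11, 18, 21 and X (adjusted p = 0.18), which takes out ALAS2 on chromosome X and FECH on chromosome 18. It kept its call without chromosomes 8, 11, 12, 15 and 21 (0.0036). The globins went both ways, with 3 of 8 higher and 3 lower (camera adjusted p = 0.75): the embryonic HBZ rose by 1.33 ± 0.15, and the fetal HBG1 fell by 0.40 ± 0.051. Reads of near-identical globin copies can be lost or split, so their values are uncertain.

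Megakaryocyte genes were mostly lower, with 7 of 9 fallen and 1 risen (camera adjusted p = 0.00029, and adjusted p = 0.2 with an estimated correlation). Besides RAB27B, the transcription factor RUNX1 fell by 0.62 ± 0.036. Without chromosomes 8, 11, 18, 21 and X, where both genes lie, the call was lost (adjusted p = 0.2), and without chromosomes 8, 11, 12, 15 and 21 it was not (0.0037). Of the monocyte and granulocyte genes, 5 of 9 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.1), with SPI1 at 0.64 ± 0.086, AZU1 at 0.93 ± 0.14 and LYZ at -0.66 ± 0.093. Of the stem and progenitor genes, 2 of 10 rose and 5 fell (camera adjusted p = 0.22), with ALDH1A1 at 0.89 ± 0.054, MYB at -0.33 ± 0.028 and CD44 at -0.99 ± 0.12.

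Among drug transporters, 5 of 13 rose and 2 fell (camera adjusted p = 0.16). The lipid transporter ABCA3 rose by 0.43 ± 0.037 and SLCO1A2, an uptake carrier, by 0.83 ± 0.085, while the efflux pump ABCC1 fell by 0.14 ± 0.033. ABCB1, the classical multidrug efflux pump, was near the detection limit at 0.954 ± 0.37 against 0.824 ± 0.013 CPM (SD, n = 3 each) and did not pass the test (log2 fold change 0.19 ± 0.39, edgeR adjusted p = 0.74). Its sign turned without over-expression replicate 1 (-0.02). ABCG2 had 4 counts over the over-expression libraries and 2 over the controls, too few to test. BCR (-0.04 ± 0.028, edgeR adjusted p = 0.3) and ABL1 (-0.02 ± 0.027, edgeR adjusted p = 0.53), whose counts include any fusion transcript, did not pass the test. After a GC and length correction chosen after seeing the data, they passed it at -0.18 and -0.10, and at -0.15 and -0.07 with TMM scaling factors taken after that correction.

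Of the survival members of the BCL2 family and related inhibitors, 1 of 8 rose and 2 fell (camera adjusted p = 0.55). BCL2L1 rose by 0.23 ± 0.044 (edgeR adjusted p = 2.2e-05), MCL1 fell by 0.27 ± 0.031 (edgeR adjusted p = 7.5e-11) and BIRC5 fell by 0.14 ± 0.038. Of the death-promoting members, 4 of 9 rose and 3 fell (camera adjusted p = 0.32), with BBC3 at 0.81 ± 0.069, BMF at 1.10 ± 0.1 and BAK1 at -0.50 ± 0.09.

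STAT5 targets, genes that the kinase of the BCR-ABL1 fusion is known to keep active through STAT5, were higher in 9 of 13 cases and lower in 1 (camera adjusted p = 6.7e-09, and adjusted p = 0.073 with an estimated correlation). The feedback inhibitor SOCS1 rose by 1.61 ± 0.074 and PIM2, a survival kinase, fell by 0.25 ± 0.04. The largest rise was that of the repressor BCL6 (2.15 ± 0.057), which STAT5 is known to repress rather than induce in several blood cells. Outputs of the ERK pathway went both ways, with 4 of 13 higher and 6 lower (camera adjusted p = 0.76): EGR1 rose by 0.50 ± 0.043, and CCND1 fell from 15.8 ± 1.9 to 3.25 ± 0.054 CPM (SD, n = 3 each). Immediate early genes rose in 9 of 14 cases and fell in 1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.26 with an estimated correlation), with JUN at 0.76 ± 0.04, KLF6 at 0.63 ± 0.043 and FOSB at -0.92 ± 0.11.

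ATF4 targets, which serve amino acid supply and the integrated stress response, rose in 19 of 21 cases and fell in none (camera adjusted p = 4.7e-16, and adjusted p = 0.073 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, rose from 94.3 ± 1.7 to 198 ± 10 CPM, and the pseudokinase TRIB3 from 167 ± 4.9 to 275 ± 11 CPM (SD, n = 3 each). Genes of the unfolded protein response of the endoplasmic reticulum were divided, with 5 of 16 higher and 6 lower (camera adjusted p = 0.26): SEL1L rose by 0.72 ± 0.042, and the chaperones CALR and PDIA4 changed by -0.49 ± 0.028 and -0.55 ± 0.033. Heat shock genes fell in 10 of 14 cases and rose in none (0 and 11 adjusted over the list alone; camera adjusted p = 6.5e-09, and adjusted p = 0.071 with an estimated correlation). The chaperones HSP90AA1 and HSPA8 changed by -0.58 ± 0.026 and -0.38 ± 0.026.

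Targets of p53 rose in 7 of 15 cases and fell in 1 (9 and 2 adjusted over the list alone; camera adjusted p = 7.3e-05, and adjusted p = 0.073 with an estimated correlation), although K562 is known to lack functional p53. GDF15, a secreted stress factor that other stress pathways also induce, rose from 127 ± 2.4 to 567 ± 15 CPM (SD, n = 3 each), the antiproliferative BTG2 rose by 1.19 ± 0.054, and AEN fell by 0.20 ± 0.048. Hypoxia response genes rose in 10 of 19 cases and fell in 2 (camera adjusted p = 0.0028, and adjusted p = 0.18 with an estimated correlation), including VEGFA (0.68 ± 0.032) and BHLHE40 (0.59 ± 0.043). Glycolysis genes fell in 9 of 20 cases and rose in 2 (2 and 10 adjusted over the list alone; camera adjusted p = 0.03, and adjusted p = 0.2 with an estimated correlation). HK2 fell by 0.60 ± 0.043 and LDHA fell by 0.32 ± 0.028, whereas ENO2 rose by 0.97 ± 0.069. The glycolysis list lost its call without chromosomes 8, 11, 18, 21 and X and without chromosomes 8, 11, 12, 15 and 21 (adjusted p = 0.11 in both). Both sets take out members of the list, LDHA on chromosome 11 in both and ENO2 on chromosome 12 in the latter.

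Ribosomal protein genes rose in 38 of 45 cases and fell in 1 (39 and 1 adjusted over the list alone; camera adjusted p = 5.7e-21, and adjusted p = 0.2 with an estimated correlation). RPL8 rose by 0.47 ± 0.028, and RPS3 fell by 0.11 ± 0.026. Mitochondrially encoded mRNAs rose in 10 of 13 cases and fell in none (11 and 0 adjusted over the list alone; camera adjusted p = 1.4e-08, and adjusted p = 0.23 with an estimated correlation), with MT-CO3 at 0.62 ± 0.034 and MT-ND2 at 0.49 ± 0.035. Several shares of the libraries that can follow RNA preparation moved with the groups. The mitochondrial chromosome took 3.12% ± 0.192 of the counts against 2.61% ± 0.16, the nuclear noncoding RNA MALAT1 took 2.6% ± 0.0265 against 1.97% ± 0.0289, and the 10 most abundant genes took 6.9% ± 0.135 against 5.73% ± 0.0954 (SD, n = 3 each). Nuclear genes of oxidative phosphorylation were mostly under the threshold, with 4 of 33 higher and 9 lower (camera adjusted p = 0.25), for example COX6C at 0.22 ± 0.04 and SDHD at -0.49 ± 0.051. Many ribosomal protein genes have pseudogene copies and mitochondrial genes have nuclear copies, so reads that map to several places can be missing from them.

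DNA replication genes fell in 16 of 29 cases and rose in 3 (3 and 18 adjusted over the list alone; camera adjusted p = 0.00077, and adjusted p = 0.18 with an estimated correlation). MCM4, a subunit of the replicative helicase, fell by 0.28 ± 0.028 and RRM2, of ribonucleotide reductase, fell by 0.45 ± 0.048, whereas the licensing factor CDT1 rose by 0.39 ± 0.033. Mitosis genes showed no common direction, with 4 of 24 higher and 6 lower (camera adjusted p = 0.76): CENPE rose by 0.35 ± 0.04, and BUB1 and CCNB1 changed by -0.32 ± 0.03 and -0.31 ± 0.035. DNA repair genes fell in 10 of 24 cases and rose in 6 (camera adjusted p = 0.042, and adjusted p = 0.2 with an estimated correlation), with PARP1 at -0.45 ± 0.029, ATM at -0.27 ± 0.029 and XRCC1 at 0.43 ± 0.076. That call was also lost without the control column numbered 1 (adjusted p = 0.055), without chromosomes 8, 11, 18, 21 and X (adjusted p = 0.21) and without chromosomes 8, 11, 12, 15 and 21 (adjusted p = 0.23). Replication-dependent histone genes, whose near-identical copies make their counts uncertain, rose in 8 of 17 cases and fell in 5 (8 and 7 adjusted over the list alone; camera adjusted p = 0.39). The list passed without over-expression replicate 3 (adjusted p = 0.024).

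Cell adhesion and matrix genes rose in 10 of 20 cases and fell in 5 (camera adjusted p = 0.016, and adjusted p = 0.2 with an estimated correlation). Fibronectin, FN1, rose from 122 ± 1.9 to 453 ± 8.6 CPM (SD, n = 3 each), LAMB1 rose by 0.55 ± 0.038 and ANXA2 fell by 0.31 ± 0.032. Genes of class I antigen presentation fell in 5 of 7 cases and rose in none (camera adjusted p = 0.011, and adjusted p = 0.18 with an estimated correlation), including HLA-E (-0.31 ± 0.044) and PSMB9 (-0.95 ± 0.18). Cancer-testis and placental antigens fell in 7 of 12 cases and rose in 1 (2 and 7 adjusted over the list alone; camera adjusted p = 0.0037, and adjusted p = 0.17 with an estimated correlation). MAGEC1 and PAGE1, which belong to families of similar copies, changed by -1.02 ± 0.058 and -1.64 ± 0.12, and PRAME rose by 0.15 ± 0.025.

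**Figure D2:**
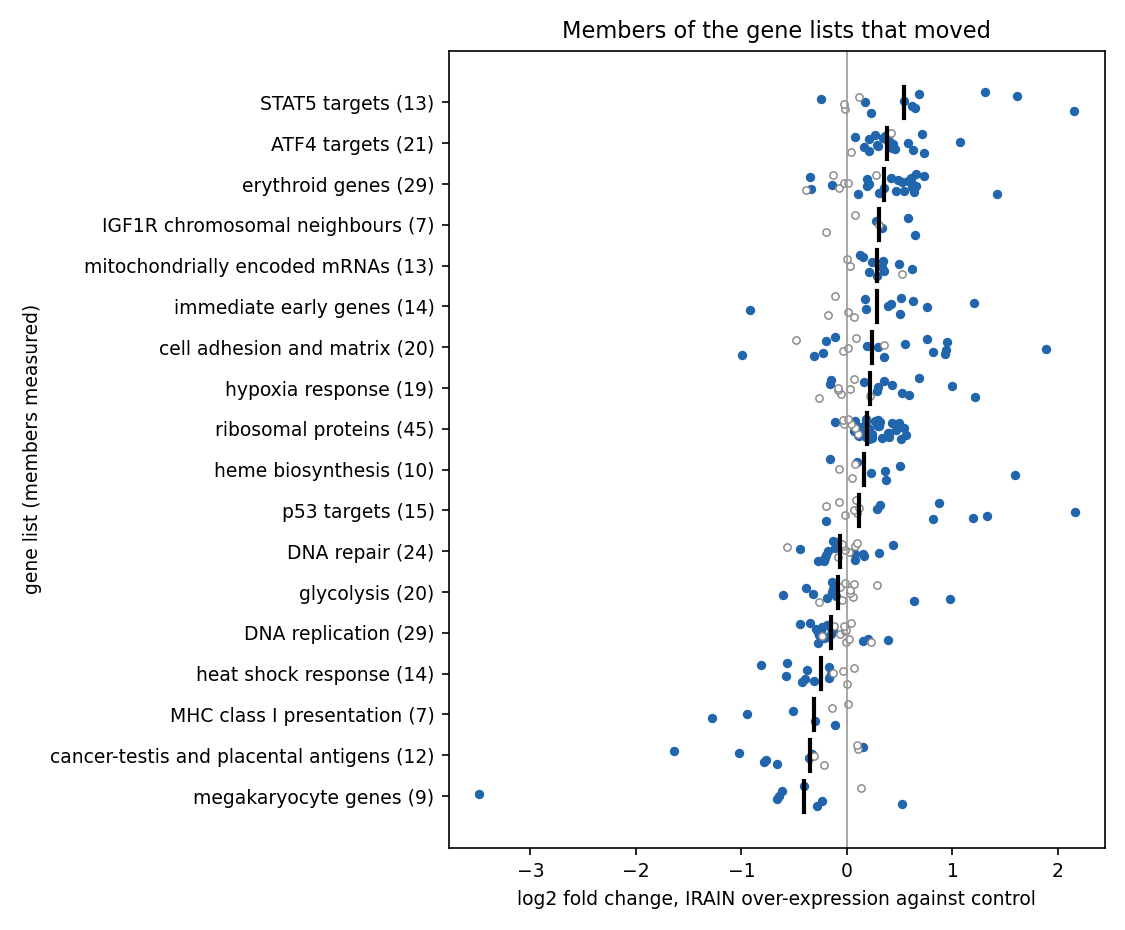
Log2 fold changes (horizontal axis, over-expression against control) of the measured members of the 18 gene lists that moved by camera with its preset correlation. Filled points passed the edgeR test at an adjusted p of 0.05, open points did not, and black bars mark list medians; 11 lists moved up and 7 down, and with an estimated correlation none was called (smallest adjusted p = 0.0712).

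The remaining lists did not pass the test. Interferon-stimulated genes rose in 2 of 18 cases and fell in 6 (camera adjusted p = 0.13), with IFITM3 at -0.58 ± 0.041 and OAS3 at -2.49 ± 0.27. Inflammatory genes of the NF-kB pathway rose in 5 of 13 cases and fell in none (6 and 0 adjusted over the list alone; camera adjusted p = 0.068), with CXCL8 at 1.62 ± 0.21 and NFKB2 at 0.42 ± 0.05. This list passed without over-expression replicate 1 (adjusted p = 0.031), with a filter of 1 CPM in 3 libraries (adjusted p = 0.046) and without chromosomes 8, 11, 12, 15 and 21 (adjusted p = 0.044). NRF2 targets were divided, with 6 of 15 higher and 6 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.61): AKR1C3 rose by 1.67 ± 0.082, though its similar family members can share reads, and NQO1 fell by 0.73 ± 0.068. For cholesterol synthesis 3 of 21 genes rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.37), with LSS at -0.38 ± 0.049. For the TGF-beta response 5 of 15 rose and 1 fell (camera adjusted p = 0.12), with TGFBI at 2.27 ± 0.21. The WNT response had 4 of 10 higher and 1 lower (camera adjusted p = 0.55), with MYC at 0.17 ± 0.031, and the NOTCH response 2 of 11 higher and 4 lower (camera adjusted p = 0.38), with HES1 at 0.94 ± 0.076 and JAG2 at -0.35 ± 0.049.

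Of the markers of other cell types, the epithelial list did not pass the test. Of its genes, 3 of 7 rose and none fell (camera adjusted p = 0.12), with KRT18 at 0.40 ± 0.037 and KRT19 at 0.37 ± 0.053. The other such lists had fewer than 5 measured genes and were not tested as lists. Of the fibroblast genes 1 of 4 rose and 3 fell, of the T lymphocyte genes 1 of 4 rose and 1 fell, of the B lymphocyte genes 1 of 2 rose, and of the endothelial genes 2 of 4 fell. Among them COL5A1 fell by 1.10 ± 0.05, with 87.9% of its reads on the opposite strand in the library with strand counts, while ZAP70 rose by 1.87 ± 0.22, CD22 rose by 1.07 ± 0.19 and PECAM1 fell by 0.96 ± 0.1. Of 3 class II presentation genes 1, CD74, passed the test (-0.98 ± 0.4, edgeR adjusted p = 0.043), at 0.57 ± 0.12 against 1.13 ± 0.039 CPM (SD, n = 3 each). Its call was lost under DESeq2 (adjusted p = 0.25), with no filter (0.081), with the replicate block (0.057) and in all fits with 1 library left out (0.081 to 0.16) but that without over-expression replicate 1, and 71.4% of its few reads lay on the opposite strand in the library with strand counts. Of 2 metallothionein-list genes none passed the test.

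With the correlation between the genes of a list estimated from the data, camera called 0 of the 38 tested lists. The smallest adjusted p was then 0.0712, and 10 lists had an unadjusted p under 0.05, all of them among the 18 called with the preset correlation. Estimated correlations were below the preset 0.01 for erythroid genes (-0.019), heat shock (0.0027), p53 targets (-0.049), glycolysis (0.0061), DNA repair (0.0069) and cancer-testis antigens (-0.044). They were above 0.01 for the other called lists. A higher correlation thus cannot account for the lost calls of the lists named. With an estimated correlation, camera also uses only the 4 residual degrees of freedom, and this step was not tested separately. The rotation test fry, which asks whether the genes of a list move on balance one way and makes no comparison with other genes, called 31. The median and the test differed in sign for 6 lists, namely the death-promoting BCL2 members, ERK outputs, mitosis, cholesterol synthesis, NRF2 targets and histones, and the mean and the test for 2 others, the globins and the WNT response.

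Changes were uneven along the genome. On chromosome 11, 69.6% of 710 genes above 4 CPM lay under the median log2 fold change of the other chromosomes' genes (exact 95% interval 66 to 72.9), and the chromosome's median was -0.140. Chromosome 21 was also lower (median -0.136), and chromosomes 8, 12 and 15 were slightly higher (medians 0.063, 0.026 and 0.038). These 5 of 23 chromosomes passed a permutation test over genes, which are not independent replicates, with adjusted p = 0.0038 for chromosomes 8, 11 and 21, whose p of 0.0005 is the smallest that 2000 resamples can give. The adjusted p was 0.039 for chromosome 12 and 0.032 for chromosome 15 in the same permutation test. Of the genes named above, HBG1, CD44, CCND1, IFITM3, RPS3, SDHD, LDHA, HSPA8 and ATM lie on chromosome 11 and fell, while SPI1 on the same chromosome rose.

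**Figure D3:**
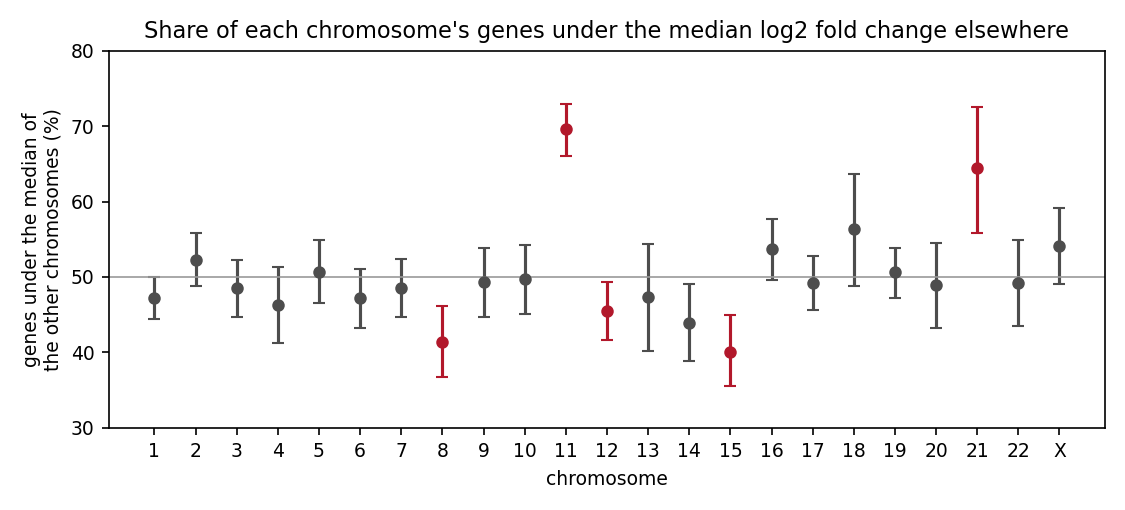
Percentage of each chromosome's genes above 4 CPM (vertical axis, from 30 to 80) whose log2 fold change lay under the median of the other chromosomes' genes, with exact 95% binomial intervals; red marks a permutation adjusted p under 0.05. Chromosome 11, at 69.6%, and chromosome 21, at 64.4%, lie highest.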

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

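The tests of antisense reads and of the chromosome end in this part were chosen only after the results were seen. The deposited table with strand counts of 1 library lies outside the comparison and holds reads on the strand opposite to 3 genes discussed in the report. For IRAIN, 74 reads lay on its own strand and 20 on the other. For IGF1R, 125 of 633 reads lay on the other strand (19.7%), against 15.1% of all strand-assigned counts. Shares of this size also occurred at other named genes, such as BCR (21.4%), CDT1 (21.1%) and JUN (20.8%), while many, such as TFRC (5.38%), were lower. The shares of IRAIN (21.3%) and IGF1R thus do not stand out as antisense signal at this locus. For SPATA31C2, 68 reads lay on the other strand and 9 on its own. No control library has such counts, so none of these shares can be compared between groups.

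IGF1R was higher in all 3 over-expression libraries. Antisense IRAIN reads counted to IGF1R could raise its strand-ignored count. In the library with strand counts, reads on the strand of IGF1R alone gave 39.9 CPM (95% interval 36.5 to 43.6, counting error only), over the highest control at 30.2 CPM with both strands counted, which argues against antisense reads as the whole source in that library and says nothing of the other 2. A shift of the whole chromosome end was set against the 33 other tested genes within 3 Mb on either side. Their median log2 fold change was 0.26 (bootstrap 95% interval 0.08 to 0.33) against 0.69 for IGF1R, and 8 of them rose and 1 fell. That interval covers the median and not the spread of single genes, and the neighbour ARRDC4 rose by 0.65 ± 0.048 (SE). A uniform shift at the median would thus fall short of the rise, but a shift that varies between genes is not excluded. An effect of IRAIN on IGF1R, and sense reads that stem from the construct itself, stay open, as the inserted sequence is not known here.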

How the results depend on the processing

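The GC and length correction in both forms, leaving out chromosomes and the demand for 2-fold were chosen after seeing the data. The count of 7217 changed genes (3734 higher, 3483 lower) stayed within 1.5 times under RLE factors, limma-voom, both filters, the stricter p, the GC and length correction (7513) and each library left out (6334 to 6749). The GC and length correction gave 3232 higher and 4281 lower, but it also moved the median log2 fold change of all tested genes from -0.00103 to -0.0295. With TMM factors taken after it, that median was 0.00226 and 7404 genes passed, 3747 higher and 3657 lower. DESeq2 gave 4805 (2463 higher, 2342 lower) over 22041 genes with an adjusted p, and 4735 of its calls were shared. The cause was not tested. The test against a 1.5-fold change gave 689 (447 higher, 242 lower) and the demand for at least 2-fold 876 (314 lower, the rest higher), by construction. Without chromosomes 8, 11, 18, 21 and X, 5878 genes of 15604 tested passed, and without chromosomes 8, 11, 12, 15 and 21, 5734 of 14806. No shared call changed sign except 5 genes under the GC and length correction and 2 with TMM taken after it.

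Libraries of equal replicate number showed no sign of pairing, as their deviations over all tested genes correlated at -0.042, -0.0057 and -0.013. The replicates differ by little more than counting noise, which can hide a shared deviation, so pairing is not excluded. With the replicate block, 7077 genes passed (3661 higher, 3416 lower), all 18 lists stayed called, and of the named genes 1, CD74, lost its call (adjusted p = 0.057).

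IRAIN kept direction and call in every alternative run for it. IGF1R kept them in all but the demanding thresholds, where at 0.69 it did not pass the test against a 1.5-fold change (adjusted p = 0.23) and lay under 2-fold. Of the 157 named genes, 13 lost their call under DESeq2, 2 without a filter, and 3 to 6 with 1 library left out. Under each form of the GC and length correction 2 lost it and BCR and ABL1 gained one. Of the 18 lists, 0 were called with an estimated correlation (10 at an unadjusted p under 0.05) and 31 lists by fry, which asks another question. For 16 of the 18, the estimated correlation gave the highest adjusted p of all alternatives, and the highest of any was 0.26. Lists called numbered 17 to 19 with 1 library left out and 12 without chromosomes 8, 11, 18, 21 and X, where cancer-testis antigens had too few genes for a value. Without chromosomes 8, 11, 12, 15 and 21, 16 lists were called, 15 of them among the 18, and the IGF1R neighbours had no value. Depth limits IRAIN, at 0 or 1 counts per control library, and ABCB1 and ABCG2.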

Other observations

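The copy number explanation was raised only after the chromosome pattern was seen, and its test was then fixed before its result. The GC and length correction and, with it, the difference of chromosome 11 from the other chromosomes were chosen only after the results were seen. In the scan along the genome, 13 runs of neighbouring genes passed the permutation threshold, 4 of them on chromosome 11, holding 1008 genes (8.14% of those scanned and 10.4% of the changed ones). The largest window median was -0.36, near the short-arm end of chromosome 11, where 111 genes starting from 127204 to 8612037 had a median of -0.20 and 75.7% had a log2 fold change below 0. A second run of 138 genes on chromosome 11, starting from 76800364 to 118998142, had a median of -0.20, and 95 genes on chromosome 18 had one of -0.17. On the long arm of chromosome 8, 50 genes starting from 134792020 to 144314584 had a median of 0.19, and on chromosome 12, 57 genes starting from 55820960 to 57755098 also had a median of 0.19. After the GC and length correction, with TMM factors taken afterwards, these medians were 0.12 on chromosome 8 and 0.14 on chromosome 12. The 2 runs on chromosome 19 were less uniform, with medians of -0.09 and -0.08 and 56.9% and 62.2% of their genes below 0.

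For the lower expression along chromosome 11, a trend with GC content and length would shrink the chromosome's median once removed, yet the median was -0.183 after the correction against -0.140 before. As the correction lowered most chromosomes alike, the difference from the other chromosomes is the fairer measure, and it was -0.150 after against -0.143 before. Copy number that differs between the 2 cell populations predicts the same shift in genes that the scan had left out. The 315 tested genes of chromosome 11 at 4 CPM or less differed by -0.13 in median from 5632 such genes elsewhere (bootstrap 95% interval -0.17 to -0.07). A lower copy number in part of the over-expression cells would give this, and so would a higher one in part of the control cells. Regulation of many genes along the chromosome predicts the same and stays open, since no DNA measurement was analysed here.

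The number of changed genes, 7217, was set against other splits of the 6 libraries into 3 and 3. Of the 10 splits, 1, the real one, gave as many. The highest of the others was 0 by edgeR and by limma-voom, with 218 to 329 genes at an unadjusted p under 0.05 by edgeR, and 10 splits are too few for a share under 0.05. Every other split also mixes over-expression and control libraries, so their difference inflates the spread within its groups. Few calls there were fixed in advance, and nothing about chance is concluded from the splits. Removing the GC and length trend left 104.1% of the number (7404 genes with TMM factors taken afterwards), against that trend as the whole cause. Differences between the cultures other than IRAIN stay open. Of these, copy number was examined for chromosome 11 alone, through expression, and an empty vector in 1 group was not tested.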
